A study of Mus musculus with 6 samples.

How the data were processed

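Total RNA of embryonic mouse hearts was purified with a DNase digest, poly(A) RNA was selected with magnetic beads, and libraries were made with the NEBNext Ultra RNA kit and 13 PCR cycles, per the labels' protocols. Sequencing was on an Illumina NextSeq instrument, per the series design. The submitters' processing notes name FastQC, DESeq2 and the mouse build mm10, with no versions. The aligner, the read counter and the annotation are not given in the sources used here, nor is whether strand was used in counting, so reads of overlapping or near-identical genes may be split or shared.

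The authors deposited a table of FPKM per gene and library and a table of their comparison of the groups. The authors' deposited table gives a mean normalized count, a log2 fold change with its standard error, a p-value and an adjusted p-value, per the file headers, and a mark that separates genes by a mean count of about 10.0. Positive fold changes there mean higher in the knockout-labelled libraries, since 95.2% of the 12121 tested genes had the same sign as in the FPKM. Its fold changes are narrowed toward 0, with standard errors up to 0.311. From the values, the deposited FPKM were scaled by size factors between libraries rather than by each library's total, and sum to between 429622 and 788996. Whole reads could be recovered from both tables: all of the 94235 values above 0 came out whole, 100% within a tolerance of 0.01, and size factors recomputed from those reads matched. Recovered totals ranged from 3414257 to 7732674 reads per library, and counting error at this depth is small for all but genes of few reads. PCR copies cannot be told from separate molecules, so read numbers cover counting error only. Of 10 hemoglobin genes in the table, 8 are listed at 0 in every library.

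Groups and replicate numbers were taken from the labels. The main test, fixed before the data were examined together with the gene lists and the rule for named genes, was limma (version 3.58.1, R 4.3.3; lmFit and eBayes with an intensity trend) on log2(FPKM + 0.5), two-sided, with group as the factor. Genes needed 1 FPKM or more in at least 3 libraries. P-values were adjusted by Benjamini-Hochberg and genes called under 0.05. Fold changes on this scale understate the change of low genes. A count test was not used as the main test because the deposited unit is FPKM. Means are given with SD over 3 libraries, fold changes with the moderated SE. Medians of the atrial genes and ERK targets carry an SE over genes, which are not independent replicates.

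Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists with at least 4 tested members, and again with an estimated correlation. At the preset value 10 lists were called, 6 higher and 4 lower; with an estimated correlation 0 held. The lists covered p53 targets, cytokinesis, mitosis, replication, histones, cardiac stress, sarcomere, calcium and ion channels, cardiac transcription factors, extracellular matrix, markers of cell types in and around the heart, metabolism, stress and immune responses, apoptosis, DNA repair, inhibitors of the cell cycle, relatives of Gas2l3 and its neighbours, and genes of sex. Some lists share members. Named genes were Gas2l3, then the called genes with the largest changes whose groups did not overlap; as fewer than 5 passed in either direction, the 5 smallest p of each direction were named as not called. Up to 4 members of each list with the smallest p were added. Predicted genes and pseudogenes were not named. Genes named from the authors' deposited table, atrial genes and ERK targets fall outside this rule and were chosen after their values were seen.

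Replicate numbers were checked as pairs: deviations from the group means correlated across genes at 0.472, 0.443 and 0.185 for libraries of the same number, each above 0.1, and each library correlated best with its own number. The pairing comes from the data, as the labels only number the samples, and a fit with the replicate number as a block was run beside the fit without it. GC content came from the longest GENCODE M21 transcript of each symbol on GRCm38, the same build as mm10, and was found for 11709 of the tested genes (96.6%). Trends were removed from each library by loess (span 0.3) on GC content and on the length implied by reads per FPKM. Before removal, deviations from the gene mean correlated with GC content at −0.474 and −0.481 in both replicates 1. Correlations with log length were −0.313 and −0.417 in both replicates 2. In both replicates 3 those with GC content differed, at 0.702 and −0.159. The pair correlations were taken before removal, so shared trends may enter them. Coordinates are from the same annotation, 1-based. Alternatives were pseudocounts of 0.1 and 1, no filter, a mean of 5 FPKM or more, other scalings between libraries, the replicate block, each library left out in turn, library weights, no intensity trend and an adjusted p under 0.1. Chosen after seeing the data were removal of GC and length trends, sex as a covariate, voom on recovered reads and a fit of 4 libraries.

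The scripts were tested on simulated reads with the means, depths and spread of these libraries and known fold changes. At the real spread, 1.01% of 99 genes with a log2 fold change of 1 and 35.4% of 99 with 2 were called among 11968 genes, with 0 false calls; 5.05% of unchanged genes had an unadjusted p under 0.05. For lists, values were simulated on the log2 scale with each gene drawn independently. A shifted list was called in 20 of 20 simulations and an unshifted one in 0. As these simulations held no correlation between genes, they do not show how often lists are wrongly called in these data.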

Results

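Poly(A) RNA of hearts from mouse embryos late in gestation (E18.5) was sequenced in 6 libraries, 3 labelled wildtype and 3 labelled Gas2l3 −/−, on a C57/Bl6 background. The deposited table held 24421 genes in FPKM, of which 12121 reached 1 FPKM in at least 3 libraries and were tested. Whole reads recovered from the values came to 3414257 in wildtype-labelled replicate 1, 7605745 in replicate 2 and 7732674 in replicate 3. The knockout-labelled libraries held 5964785, 5514800 and 6483168 reads in replicates 1, 2 and 3. The labels number the samples within each group and do not say whether each came from a separate embryo, so p-values measure the spread between these samples. Y-linked genes were above 1 FPKM in 1 library of each group and Xist prevailed in the other 2 of each, so by these genes the sexes were balanced between the groups.

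Gas2l3 encodes a protein that binds actin and microtubules, and the series title ties its loss to cytokinesis of cardiomyocytes. Reads of Gas2l3 were present in each of the 6 libraries, and the groups overlapped. Gas2l3 (chromosome 10, 89408823 to 89443967, mm10, ENSMUSG00000074802.11) stood at 10.3, 4.12 and 2.48 FPKM in wildtype-labelled replicates 1, 2 and 3, and at 4.03, 2.99 and 3.06 FPKM in the knockout-labelled replicates. Between 102 and 262 reads per library lay behind these values. The log2 fold change was −0.47 (SE 0.44, adjusted p = 0.966, limma), and without wildtype-labelled replicate 1 it was 0.047. In FPKM as deposited, wildtype-labelled replicate 3 lay below every knockout-labelled library. Gas2l3 is low in GC content (41.7%), where that library's values were low; with trends on GC content and length removed it stood at 1.93 on the log2 scale, above knockout-labelled replicates 1 (1.80) and 3 (1.89) and below replicate 2 (2.02), so the groups still overlapped. Paired by replicate number, the knockout-labelled library was lower in 2 of 3 pairs as deposited and in 3 of 3 with trends removed (−0.53, SE 0.25, adjusted p = 0.476 with the replicate block). The labels do not say which part of the gene was deleted, and a value per gene includes reads from any exons that remain, so it cannot check the genotype. All directions below therefore refer to the libraries as labelled.

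**Figure D1:**
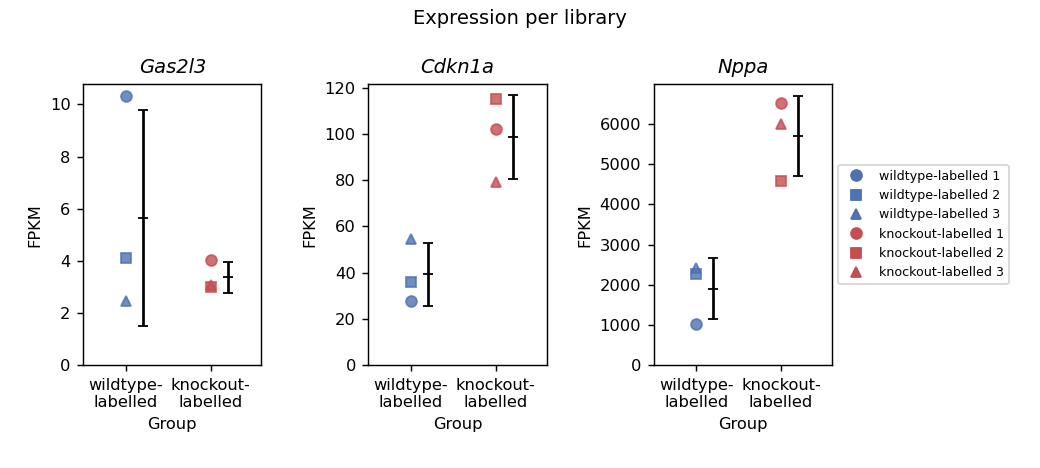
FPKM of Gas2l3, Cdkn1a and Nppa in each library (symbols), with the group mean and SD beside them (black, n = 3); each vertical axis starts at 0. Gas2l3 overlapped between the groups, while the 3 knockout-labelled libraries lay above the 3 wildtype-labelled ones for Cdkn1a and Nppa. Neither passed over all genes in the limma fit, while Nppa was called in the authors' deposited table.

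The comparison asked which genes differ in the heart when Gas2l3 is labelled as deleted. No single gene passed: limma called 0 genes higher and 0 lower at an adjusted p under 0.05 among 12121, with 394 at an unadjusted p under 0.05, 230 of them higher and 164 lower. Voom on the recovered reads also called 0, with 375 at an unadjusted p under 0.05, and the authors' deposited table called 7 higher and 2 lower. The groups did not overlap for 1183 genes, 9.76%, where chance gives 10% for unpaired libraries. As libraries of the same replicate number correlated, chance may give less here. In simulated data with the spread of these libraries, 1.01% of 99 genes with a true log2 fold change of 1 and 35.4% of 99 with a change of 2 were called. Of unchanged genes there, 5.05% had an unadjusted p under 0.05, a larger share than the 394 of 12121 here. That simulation held no pairs of libraries. Other splits that, like the real one, part all pairs of replicate numbers had 58, 88 and 111 such genes. The number at an unadjusted p under 0.05 was 1467 without wildtype-labelled replicate 1 and 250, 207 and 185 without knockout-labelled replicates 1, 2 and 3, with 0 called by limma in each.

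The genes with the smallest p were not called. Among those with higher means, Cpa4, a carboxypeptidase, was at 0.444 ± 0.0995 FPKM (SD, n = 3) in wildtype-labelled and 2.49 ± 0.0878 FPKM in knockout-labelled libraries, a log2 fold change of 1.67 (SE 0.27, adjusted p = 0.509). The small nucleolar RNA Snora44 had 1 to 3 reads per wildtype-labelled library and 6 to 13 per knockout-labelled library. The microRNA genes Mir3100, Mir6981 and Mir186 rested on 0 reads in each wildtype-labelled library and 1 to 4 in each knockout-labelled one, so no fold is given. Among those with lower means, Ppp1r1b, an inhibitor of protein phosphatase 1, was at 60.0 ± 34.6 FPKM in wildtype-labelled and 12.2 ± 1.51 FPKM in knockout-labelled libraries (log2 fold change −2.10, SE 0.41, adjusted p = 0.966). Cacng6, a calcium channel subunit, had a log2 fold change of −1.97 (SE 0.41), Klhl40 of −1.30 (SE 0.30), the carbonic anhydrase gene Car4 of −1.71 (SE 0.39) and Neurl1b of −0.89 (SE 0.22), each with an adjusted p of 0.966.

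In the authors' deposited table the 7 genes called higher were Klhdc7a, Eda2r, Ano3, Mylk4, Cpa4, Nppa and Adgrg6, and the 2 called lower were Ppp1r1b and Cacng6. Klhdc7a had the highest log2 fold change in the authors' deposited table, 1.57 (adjusted p = 0.00305), and Ppp1r1b the lowest, −1.54 (adjusted p = 0.0017). Ano3 and Klhdc7a from the authors' deposited table lay under the expression minimum used here, with means of 0.732 and 0.941 FPKM in the knockout-labelled libraries. Across the 12121 tested genes, 95.2% had the same sign in the authors' deposited table as in the limma fit.

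Genes of cell division had lower means in the knockout-labelled hearts across 3 lists. The mitosis list fell, with a median log2 fold change of −0.57 and lower means for 46 of 47 members (camera with a preset correlation, adjusted p = 3.93e-19; adjusted p = 0.111 with an estimated correlation). The replication list fell, with a median of −0.30 and lower means for 36 of 43 members (adjusted p = 1.1e-08; adjusted p = 0.123 with an estimated correlation). The cytokinesis list fell, with a median of −0.41 and lower means for 25 of 29 members (adjusted p = 4.17e-07; adjusted p = 0.184 with an estimated correlation). No member of these 3 lists was called over all genes, and 0 were called when adjusted over the list alone. The groups did not overlap for 20 mitosis, 16 replication and 9 cytokinesis members, all lower, where chance gives 10% in both directions together for unpaired libraries.

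Among the mitosis members, the kinase gene Aurka was at 33.2 ± 3.63 FPKM (SD, n = 3) in wildtype-labelled and 18.0 ± 0.995 FPKM in knockout-labelled libraries (log2 fold change −0.86, SE 0.24). Cdc20, which activates the anaphase-promoting complex, had a log2 fold change of −0.98 (SE 0.31), Troap of −0.97 (SE 0.29) and Cenpf, a kinetochore gene, of −0.89 (SE 0.27). In the replication list, Rrm2, a ribonucleotide reductase subunit, was at 83.9 ± 9.79 against 46.1 ± 1.10 FPKM, and Mcm7 of the replicative helicase at 47.5 ± 5.51 against 26.4 ± 1.40 FPKM. E2f8 and Chaf1b had log2 fold changes of −0.76 (SE 0.22) and −0.80 (SE 0.29). In the cytokinesis list, Birc5 and Cdca8 of the chromosomal passenger complex were at −0.83 (SE 0.24) and −0.84 (SE 0.27), Racgap1 of the centralspindlin complex at −0.82 (SE 0.26) and Kif20b at −0.82 (SE 0.27). Wildtype-labelled replicate 3 had the lowest mean correlation with the other libraries (0.899, against 0.935 to 0.957), and without it the mitosis median was −0.60. The mitosis median was −0.35 without wildtype-labelled replicate 1 (adjusted p = 1.72e-06, the highest over 20 alternatives). The replication median was −0.15 when libraries were rescaled to a common total, a step that moved the median of all genes to 0.15.

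**Figure D2:**
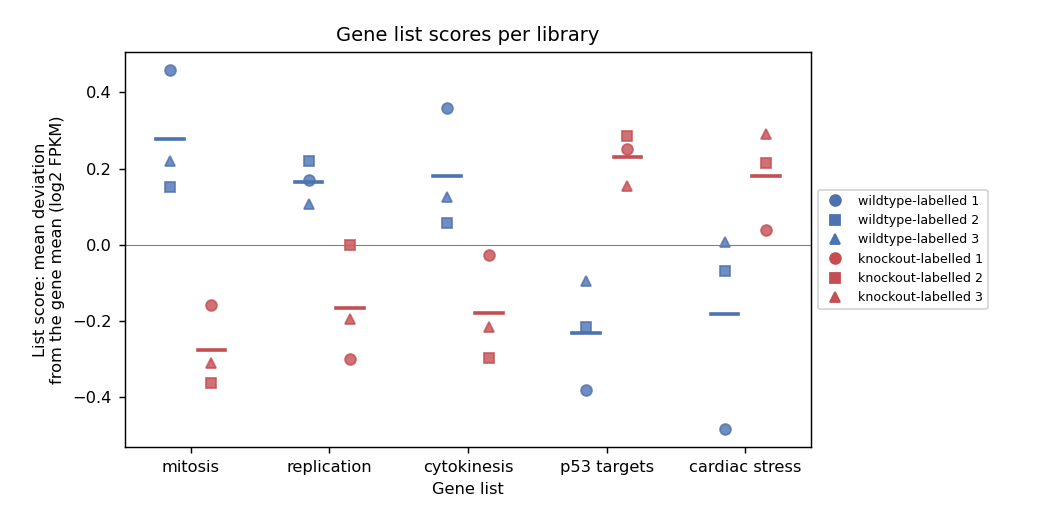
List scores per library, the mean over list members of the deviation from each gene's mean (log2 FPKM, vertical axis), for 5 lists; symbols are libraries and bars group means. In each of the 5 lists the 3 knockout-labelled libraries lay on one side of the 3 wildtype-labelled ones. An exact permutation test gave p = 0.1 for each, the smallest that 3 against 3 allows. The 5 lists were chosen among those that part the labelled groups, so the separation and this p follow from that choice. The closest cardiac stress scores were 0.0073 (wildtype-labelled replicate 3) and 0.038 (knockout-labelled replicate 1). The macrophage, interferon and matrix lists were also called, but their scores overlapped between the groups and are not drawn.

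Targets of p53, the transcription factor activated by DNA damage, had higher means in the knockout-labelled hearts. The p53 list rose, with a median log2 fold change of 0.36 and higher means for 33 of 41 members (adjusted p = 1.42e-09; adjusted p = 0.111 with an estimated correlation). No member was called over all genes, and 5 were called higher when adjusted over the list alone, a step not corrected for the number of lists. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 39.3 ± 13.6 FPKM (SD, n = 3) in wildtype-labelled and 98.8 ± 18.1 FPKM in knockout-labelled libraries. Its log2 fold change was 1.35 (SE 0.33, limma adjusted p = 0.966 over all genes and 0.0319 over the list alone). The other members called over the list alone were Eda2r at 1.72 (SE 0.37), Zmat3 at 1.02 (SE 0.22), the death receptor gene Fas at 1.18 (SE 0.29) and Pmaip1 at 1.15 (SE 0.31). The groups did not overlap for 16 higher and 1 lower of the 41 members, where chance gives 10% for unpaired libraries. The apoptosis list, 6 of whose members are also in another list, rose with a median of 0.20 (adjusted p = 0.0223; adjusted p = 0.201 with an estimated correlation), and 0 were called over all genes or adjusted over the list alone. Bcl2 was at 0.93 (SE 0.28) and Tnfrsf10b, also a member of the p53 list, at 0.83 (SE 0.27). The apoptosis call ended without wildtype-labelled replicate 1 (adjusted p = 0.191), without knockout-labelled replicate 2 (adjusted p = 0.0896) and with a mean of 5 FPKM required (adjusted p = 0.557), over a range of 0.00312 to 0.557 in 20 alternatives. Without wildtype-labelled replicate 3 its median was 0.062.

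Genes of cardiac stress rose as a list, with a median log2 fold change of 0.29 and higher means for 19 of 26 members (adjusted p = 0.00055; adjusted p = 0.201 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, was at 1904 ± 759 FPKM (SD, n = 3) in wildtype-labelled and 5703 ± 1005 FPKM in knockout-labelled libraries, a log2 fold change of 1.66 (SE 0.52, adjusted p = 0.966). In the authors' deposited table Nppa was called, at 1.15 (adjusted p = 0.0449). Gdf15 was at 1.05 (SE 0.33), and the matricellular genes Cyr61 and Ctgf at 0.73 (SE 0.25) and 0.75 (SE 0.27). Of the 26 members, 9 are also in another list, among them Gdf15 in the p53 list and Ctgf in the matrix list. The list's call ended without wildtype-labelled replicate 1 (median 0.27, adjusted p = 0.146, in a range of 1.09e-06 to 0.146 over 20 alternatives). Its median was 0.45 without wildtype-labelled replicate 2, 0.49 without wildtype-labelled replicate 3 and 0.47 with a common total. Macrophage markers, with a median of 0.39, were higher in the same comparison.

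Genes of the sarcomere fell as a list, with a median of −0.28 and lower means for 25 of 29 members (adjusted p = 0.0381; adjusted p = 0.493 with an estimated correlation). Tnni1, the slow skeletal troponin I that fetal hearts express, was at −0.94 (SE 0.58), Trim63 at −0.46 (SE 0.27) and Ldb3 at −0.46 (SE 0.29), while Myom2 was at 0.65 (SE 0.41). Tnni1 was at −0.41 without wildtype-labelled replicate 3, and Myom2 at 0.30 without wildtype-labelled replicate 2. The sarcomere call ended in 8 of 20 alternatives. It ended without wildtype-labelled replicate 1 (adjusted p = 0.187), wildtype-labelled replicate 3 (median −0.14, adjusted p = 0.136), knockout-labelled replicate 2 (adjusted p = 0.122) or knockout-labelled replicate 3 (adjusted p = 0.0585), without wildtype-labelled replicate 3 and knockout-labelled replicate 1 together (adjusted p = 0.152), with a mean of 5 FPKM required (adjusted p = 0.0663), with sex as a covariate (adjusted p = 0.0642) and under quantile normalization (median −0.13, adjusted p = 0.589), the highest p of the 20, of which the lowest was 0.00605. Calcium handling and ion channel genes (median −0.063, adjusted p = 0.486) and cardiac transcription factors (median −0.19, adjusted p = 0.0529) did not pass. The transcription factors passed, lower, in 8 of 20 alternatives (adjusted p from 0.00127 to 0.341), among them without wildtype-labelled replicate 3 (adjusted p = 0.00151) and without knockout-labelled replicate 1 (adjusted p = 0.0189). Their median ran from −0.29 (without knockout-labelled replicate 1) to −0.030 (without wildtype-labelled replicate 1) with 1 library left out. Casq2, the calcium buffer of the sarcoplasmic reticulum, was at 1.07 (SE 0.39) and the pacemaker channel gene Hcn4 at −0.63 (SE 0.27). Irx5 was at 0.71 (SE 0.27) and Irx4 at −0.67 (SE 0.32), or −0.37 without wildtype-labelled replicate 3.

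Immune and matrix lists were called in the same comparison. Macrophage markers rose, with a median of 0.39 and higher means for 11 of 13 members (adjusted p = 0.00133; adjusted p = 0.445 with an estimated correlation), among them Lyz2 at 1.43 (SE 0.43) and Ly86 at 1.01 (SE 0.32). Interferon response genes rose, with a median of 0.36 and higher means for 21 of 24 members (adjusted p = 3.55e-05; adjusted p = 0.493 with an estimated correlation), with Ifit3 at 1.26 (SE 0.46), or 0.73 without knockout-labelled replicate 2. Extracellular matrix genes rose, with a median of 0.20 and higher means for 25 of 35 members (adjusted p = 0.00363; adjusted p = 0.654 with an estimated correlation), with Lum at 0.94 (SE 0.35) and Lox at 0.70 (SE 0.28), or 0.46 without knockout-labelled replicate 3. In these 3 lists the library scores of the groups overlapped. The macrophage call ended without wildtype-labelled replicate 1 (median 0.095, adjusted p = 0.445, the highest over 20 alternatives) and with a mean of 5 FPKM required (7 members, median 0.12, adjusted p = 0.0985), and the interferon call without knockout-labelled replicate 2 (median 0.21, adjusted p = 0.0896, also the highest). The matrix call ended without wildtype-labelled replicate 1 (median 0.070, adjusted p = 0.333), wildtype-labelled replicate 2 (median 3.91e-05, adjusted p = 0.802, the highest) or knockout-labelled replicate 3 (median 0.062, adjusted p = 0.261). Medians without wildtype-labelled replicate 3 were 0.54 for matrix and 0.65 for interferon genes, and without knockout-labelled replicate 2 they were 0.33 for matrix and 0.22 for macrophage genes.

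The remaining lists of cell types did not pass. Median log2 fold changes were 0.30 for fibroblast (adjusted p = 0.0767), 0.012 for endothelial (adjusted p = 0.263), 0.031 for smooth muscle and pericyte (adjusted p = 0.98), 0.071 for epicardial (adjusted p = 0.543), 0.42 for erythroid (adjusted p = 0.329) and −0.24 for skeletal muscle markers (adjusted p = 0.349). Markers of lung, liver, thymus and fat had 4 tested members and a median of 0.32 (adjusted p = 0.513). Without wildtype-labelled replicate 3 the endothelial (median 0.41, adjusted p = 8.11e-08), fibroblast (0.37, adjusted p = 0.000679) and smooth muscle lists (0.19, adjusted p = 0.0444) passed, as did fibroblast markers without knockout-labelled replicate 1 (adjusted p = 0.0393) and erythroid markers without knockout-labelled replicate 2 (adjusted p = 0.019). Over 20 alternatives fibroblast and endothelial markers each passed in 5, smooth muscle markers in 2 and erythroid markers in 1. Without 1 library the fibroblast median ran from 0.057 (without wildtype-labelled replicate 2) to 0.38, and the erythroid median from −0.11 (without knockout-labelled replicate 1) to 0.62. Endothelial medians ran from −0.31 (without wildtype-labelled replicate 2) to 0.41. Skeletal muscle medians ran from −0.48 (without wildtype-labelled replicate 1) to −0.12 (without wildtype-labelled replicate 3), and those of lung, liver, thymus and fat from 0.073 (without knockout-labelled replicate 1) to 0.68 (without wildtype-labelled replicate 1). Within the endothelial list, Emcn was at 1.08 (SE 0.30) and Npr3, an endocardial receptor for natriuretic peptides, at 1.04 (SE 0.30). For smooth muscle and pericyte markers the median was positive while the mean was −0.017 and the test pointed downward. Lists with fewer than 4 tested members were not tested: 3 replication-dependent histone genes had a median of −0.65, 3 Schwann cell and neuron markers of −0.34 and 2 neutrophil markers of 0.92. The groups overlapped for each histone gene. Hist1h2ae had 3 to 11 reads per library and Hist1h4d 0 to 9, while Hist1h4h was at 0.14 (SE 0.74).

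Metabolic and general stress lists did not pass either. The median was −0.20 for oxidative phosphorylation (adjusted p = 0.436), −0.086 for fatty acid oxidation (adjusted p = 0.38), −0.057 for glycolysis and hypoxia (adjusted p = 0.819), −0.061 for the integrated stress response (adjusted p = 0.965), 0.15 for inflammation (adjusted p = 0.185) and −0.14 for immediate early and heat shock genes (adjusted p = 0.173). DNA repair genes had a median of −0.18 (adjusted p = 0.0613) and inhibitors of the cell cycle of −0.053 (adjusted p = 0.436). Crosslinkers related to Gas2l3 had a median of −0.11 (adjusted p = 0.51) and the neighbours of Gas2l3 on chromosome 10 of 0.22 (adjusted p = 0.0818). DNA repair genes passed, lower, in 7 of 20 alternatives, among them without wildtype-labelled replicate 3 (adjusted p = 3.76e-06) and knockout-labelled replicate 1 (adjusted p = 0.0147), and the neighbours passed in 3, among them without wildtype-labelled replicate 1 (adjusted p = 0.0277). In 1 of 20 each, oxidative phosphorylation passed without knockout-labelled replicate 2 (adjusted p = 0.0248), immediate early genes without wildtype-labelled replicate 1 (adjusted p = 0.0442), cell cycle inhibitors without wildtype-labelled replicate 3 (adjusted p = 0.0225) and inflammation with no filter (adjusted p = 0.0209). Medians with 1 library left out moved widely. Between the fits without wildtype-labelled replicate 2 and without wildtype-labelled replicate 3 they went from −0.31 to −0.013 for fatty acid oxidation, 0.13 to 0.33 for inflammation, 0.030 to −0.21 for cell cycle inhibitors and −0.25 to 0.026 for crosslinkers. For the neighbours they ran from 0.072 (without wildtype-labelled replicate 3) to 0.41 (without wildtype-labelled replicate 1). No member of any list in this or the preceding paragraphs was called over all genes, and besides the 5 p53 targets none was called when adjusted over the list alone.

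The libraries differed in how values followed GC content. In wildtype-labelled replicate 3 the median deviation from the gene mean was −0.62 on the log2 scale in the sixth of genes lowest in GC and 0.87 in the highest, while in wildtype-labelled replicate 1 it was 0.30 and −0.37. Across 11709 genes, which are not independent replicates, the log2 fold change correlated with GC content at r = −0.452. With trends on GC content and length removed, limma called 0 genes higher and 1 lower, Ppp1r1b (log2 fold change −1.68, adjusted p = 0.0461); with the replicate block as well it called 0 (adjusted p = 0.0663 for Ppp1r1b), with 922 and 1313 genes at an unadjusted p under 0.05.

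**Figure D3:**
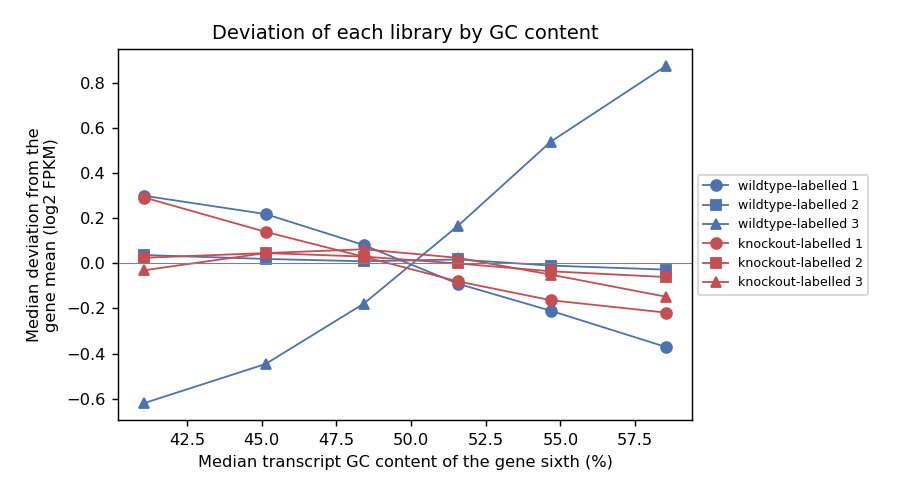
Median deviation of each library from the gene mean (log2 FPKM, vertical axis) over sixths of genes ordered by GC content of the transcript (percent, horizontal axis); each line is 1 library. Wildtype-labelled replicate 3 went from −0.62 to 0.87, against the direction of wildtype-labelled replicate 1 and knockout-labelled replicate 1.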

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

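Removal of GC and length trends (with and without the replicate block), sex as a covariate, voom on recovered reads and the fit of 4 libraries without wildtype-labelled replicate 3 and knockout-labelled replicate 1 were chosen after seeing the data. The planned count tests with edgeR and DESeq2 were not run, since the deposited unit is FPKM, though the recovered reads would have allowed them. Gas2l3 had no value where a mean of 5 FPKM was required. The p53, mitosis, replication and cytokinesis lists kept their direction and call in 20 of 20 alternatives outside library weights and the estimated correlation, with medians of 0.33 to 0.51, −0.68 to −0.35, −0.41 to −0.15 and −0.60 to −0.28, and also with library weights. The cardiac stress list did so in 19 of 20 (0.21 to 0.63). The replicate block called 0 genes (729 at an unadjusted p under 0.05) and 10 lists, and changed no other call. Limma called 0 genes in each alternative but 2: library weights called 2485 higher and 2553 lower, with weights from 0.0979 for wildtype-labelled replicate 3 to 18.1 for wildtype-labelled replicate 2, and removal of GC and length trends called 1 lower. With an estimated correlation 0 lists were called, the medians being 0.36 for p53, −0.41 for cytokinesis, −0.57 for mitosis, −0.30 for replication and 0.29 for cardiac stress; with trends removed and the replicate block as well it was 0, with 0.43, −0.43, −0.63, −0.35 and 0.39 (adjusted p from 0.224 to 0.335). The cause of these changes was not tested. Leaving out 1 library gave 7 to 15 called lists, 0 called genes, a Gas2l3 log2 fold change of −0.88 to 0.047 and a cardiac stress median of 0.21 to 0.49. Of 2628 values of named genes under alternatives 48 reversed, and of 666 of lists 52, counting a turn of the test's direction, and none of these lists was among the 10 called. Of the others, 90 values of genes passed the threshold, 89 of them with library weights, while 37 of lists passed and 40 no longer did. Genes of few reads, such as Mir3100, are limited by depth.

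Reversed values by setting were as follows. For lists the direction of the test turned, and the median given here need not have changed sign. A mean of 5 FPKM gave medians of 0.065 for smooth muscle and −0.13 for glycolysis. Quantile normalization gave −0.070 for Apoa2 and medians of 0.056 for smooth muscle, 0.016 for oxidative phosphorylation, 0.038 for glycolysis and −0.026 for integrated stress. A common total gave 0.033 for Msln, 0.20 for smooth muscle and 0.11 for integrated stress. Library weights gave −0.41 for Hist1h4h, 1.20 for Myh11, 0.11 for Smtn, 0.73 for Cspg4, −0.069 for Aldh1a2, −0.44 for Upk1b, −0.25 for Krt19, −0.029 for Bpgm and −0.16 for Aif1. They also gave −0.39 for S100a9, −0.87 for S100a8, −0.79 for Fabp7, −0.43 for Myl1, −0.55 for Ccl7, 0.22 for Macf1 and −0.20 for Nup37. Their list medians were 0.18 for calcium, 0.80 for smooth muscle, −0.24 for epicardial, 0.0014 for fatty acid oxidation, 0.088 for glycolysis and −0.0096 for integrated stress. Removal of GC and length trends, alike with the replicate block and an estimated correlation, gave 0.024 for Smtn, 0.084 for Msln, and medians of 0.093 for smooth muscle, 0.0090 for glycolysis, 0.030 for integrated stress and −0.018 for immediate early genes. Voom gave −0.058 for Hist1h4h and 0.042 for smooth muscle. The 4 libraries gave 0.39 for Egfl7, 0.081 for Cspg4, 0.066 for Msln, −0.076 for Slc25a37, −0.46 for Afp, −0.81 for Alb and 0.20 for Gas2l1. Their list medians were 0.26 for smooth muscle, −0.076 for erythroid, 0.20 for oxidative phosphorylation, 0.047 for glycolysis, 0.15 for integrated stress, 0.056 for immediate early genes and 0.044 for the Gas2l3 neighbours. Without 1 library, ranges were −0.83 to 0.84 for Hist1h4h, −0.0020 to 0.58 for Upk1b, −0.17 to 0.29 for Krt19, −0.49 to 0.75 for Apoa2, −0.14 to 0.17 for Cidea and −0.45 to 0.031 for Msln. They were −0.90 to 0.15 for Egfl7, −0.88 to 0.15 for Cspg4, −0.13 to 1.06 for Fabp7, −0.020 to 1.99 for Alb, −0.81 to 0.089 for Gas2l1 and −0.0049 to 1.37 for Afp. For lists they were −0.24 to 0.14 for calcium, −0.31 to 0.41 for endothelial, −0.30 to 0.19 for smooth muscle, −0.19 to 0.24 for epicardial and −0.28 to 0.076 for DNA repair. They were −0.37 to 0.022 for oxidative phosphorylation, −0.20 to 0.048 for glycolysis, −0.13 to 0.091 for integrated stress and −0.26 to 0.011 for immediate early genes.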

Other observations

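Tests chosen only after the result was seen were removal of GC and length trends for the mitosis and p53 lists, Nppa and the ERK targets, the exchange of libraries, and the lists of atrial genes and ERK targets.

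Targets of the ERK pathway, some of which act in its feedback, had higher means in the knockout-labelled hearts for 10 of 10 genes, with a median log2 fold change of 0.55. As these genes were chosen after values were seen, no p is given for them as a list. Spry4 was at 0.96 (SE 0.22), Etv5 at 0.99 (SE 0.23), Dusp4 at 1.17 (SE 0.28) and Phlda1 at 0.93 (SE 0.25), none called by limma over all genes (adjusted p = 0.966 each). With GC and length trends removed and the replicate block the median was 0.57 (SE 0.19 over the genes, 9 of 10 higher). This was less than 2 SE above the bound of 0.2, itself set after the data were seen. As the genes were also chosen for their values, the trends as a cause stay open. Adgrg6, called higher in the authors' deposited table, had a log2 fold change of 1.21 (SE 0.25, adjusted p = 0.966) in the limma fit.

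The 6 libraries make 10 splits into 3 and 3, the real one included, so no share under 0.05 can be reached. For genes called by limma the real split gave 0 and the highest other split 6, and 10 of 10 splits gave as many. For lists called the real split gave 10 and the highest other 13, and 3 of 10 splits gave as many; that other split exchanged wildtype-labelled replicate 3 and knockout-labelled replicate 1, and with trends removed it gave 10 against 13. The size of the mitosis median was 0.57 against 0.38 in the highest other split and that of the p53 median 0.36 against 0.32, so 1 of 10 splits was as large for each. Among the 4 splits that part all pairs of replicate numbers, the highest others were 6 genes, 9 lists, 0.25 and 0.29. The split of wildtype-labelled replicate 1 with knockout-labelled replicates 1 and 3 had 2069 genes at an unadjusted p under 0.05 against 394 in the real one, which points to a structure of the samples; with trends removed it had 1061 against 922. That split keeps both replicates 1 together, while the 3 splits that, like the real one, part all pairs had 58, 88 and 111, and with trends removed 114, 125 and 248.

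Lower mitosis and higher p53 target genes in the knockout-labelled hearts may reflect cells that stopped dividing after failed cytokinesis, a hypothesis for which cell numbers and ploidy were not analysed here. Trends on GC content and length were not the whole cause: with both removed, in the fit with the replicate block, the mitosis median was −0.63 and the p53 median 0.43, both called at the preset correlation and neither otherwise (each adjusted p = 0.224 with an estimated correlation). Medians without wildtype-labelled replicate 3 were −0.60 and 0.41, but this removal could hardly have narrowed either gap. Among wildtype-labelled libraries its p53 score (−0.0953) lay nearest the knockout-labelled ones. Its mitosis score (0.22) lay between those of replicates 1 (0.458) and 2 (0.15). With any 1 library left out, medians ran from −0.68 to −0.35 for mitosis and from 0.37 to 0.44 for p53. The mitosis median of −0.35 was that without wildtype-labelled replicate 1. Both lists stayed called at the preset correlation, so neither rested on 1 library. Chance stays open with 10 splits, as does a difference in stage or in the share of dividing cell types between embryos, which was not tested.

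Higher Nppa in the knockout-labelled hearts could come from more atrial tissue. With trends removed, 11 other atrial genes had a median log2 fold change of 0.16 (SE 0.22 over the genes, which are not independent replicates). Of these, 8 were higher, and the lowest was Sln at −1.68 (SE 0.88). Some varied widely within each group. On the log2 scale Sln ran from 4.31 to 7.96 in wildtype-labelled and from 1.88 to 7.40 in knockout-labelled libraries. Mybphl ran from 0.868 to 3.93 and from 0.749 to 4.19, while Myl4 varied less (9.92 to 10.6 and 10.2 to 10.7). The median of the 11 genes lay far under the 1.96 (moderated SE 0.37) of Nppa in the same fit. That value of Nppa also argues against GC and length trends as its cause. Among the atrial genes Myl4 was at −0.014 (SE 0.52) and Myl7 at −0.67 (SE 0.63) before removal. A response of ventricular muscle to load stays a hypothesis, as the libraries do not part the chambers.

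Gas2l3 reads in the knockout-labelled libraries, at a mean of 59.5% of the wildtype-labelled mean (102% without wildtype-labelled replicate 1), could come from exons outside the deleted part or from exchanged libraries. Values per exon were not analysed here, so the first cannot be told apart from transcription of an intact gene. For an exchange, 0 of 5 lists had library scores that overlapped between the groups, but these lists were chosen among those that part the labelled groups, so the test could hardly have come out otherwise and decides nothing. As deposited, exchanging wildtype-labelled replicate 3 and knockout-labelled replicate 1 gave Gas2l3 means of 6.16 against 2.84 FPKM; with trends removed the log2 gap in Gas2l3 was 0.45 against 0.53 as labelled. That grouping puts both replicates 1 on the same side, unlike the labelled one, so these values do not decide either.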
